A study of Mus musculus with 3 samples.

How the data were processed

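RNA was measured by sequencing in primary hepatic stellate cells, the retinoid-storing pericytes of the liver that become matrix-producing cells after injury. Per the labels' protocols, the cells came from male C57BL/6 mice 24 weeks old, by perfusion with collagenase and pronase and a density gradient. Liver macrophages were then depleted with magnetic beads against CD11b. The cells were kept for 3 days in medium with 10% serum and then for 24 h without serum, per the labels' protocols. There is 1 library for each of 3 genotypes: wild type, TLR4-/- and CD44-/-. The series text speaks of triplicates and of Illumina instruments, while the extraction protocol names a BGISEQ-500 preparation. The genotypes listed in the series text give TLR4-/- in 2 places and CD44-/- in none, so the genotypes used here are those of the sample labels. Whether animals or cultures were pooled in a library, and which knockout alleles were used, is not given in the sources used here.

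The authors deposited for each library a gene table with an expected count, an estimated read number that need not be whole, and an FPKM value, fragments scaled by transcript length and library total. Per the submitters' processing notes, RSEM was used with the mm10 build, and its version is not given in the sources used here. The deposited tables also hold a transcript length per gene, and per the file headers each gene is given by its Entrez number and RefSeq transcripts. Each table lists genes with an FPKM of at least 0.01, and a gene missing from a table was set to 0. RSEM shares reads between similar transcripts, so genes with near-identical copies or antisense partners are uncertain. Strand handling is not given in the sources used here.

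Expected counts summed to 24078669 in the wild-type library, 23659074 in the library labelled TLR4-/- and 21460725 in the CD44-/- library. FPKM was recomputed from the count and the length, with a scale and a length reduction both fitted to each library. It lay within 2% of the deposited FPKM for 100% of genes with FPKM of at least 1 and length over 200 bases. The scale was fitted to the deposited values, so this does not check it against the library total. Of 17870 genes listed in any library, 17824 matched a symbol in the RefSeq gene table of GRCm38.p6, the build mm10 also names, and the 46 others held at most 0.262% of a library's reads.

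With 1 library per genotype there was no replicate check, and no test across genes was run. Differences were described by a size rule fixed before the data were examined: log2 of the ratio of FPKM + 1 of at least 1 or at most -1, among genes with FPKM of at least 1 in either library. This scale understates the change of low genes. Log2 ratios of genes and lists keep the added 1 unless another setting is named. Ratios and fold values of named genes are ratios of FPKM without the added 1. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals on the rounded expected counts and cover counting error only. For a library with no read, the bound uses 3 counts, which is 0.125 CPM in wild type, 0.127 in the library labelled TLR4-/- and 0.140 in CD44-/-.

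For each of 35 gene lists fixed before the data were examined, the median log2 ratio was placed among 10000 random lists of the same size, matched in 20 bins of mean expression. A list was said to stand apart below percentile 2.5 or above 97.5. List genes move together, so this describes these libraries and is not a test. Of 619 list entries, 582 matched a gene and 476 were measured. Lists with fewer than 3 measured members got no percentile, and the mitochondrially encoded list had 0 of 13 members matched.

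Named genes were chosen by a rule fixed in advance. For each knockout-labelled library against wild type, it took the 10 largest and 10 smallest log2 ratios among genes with FPKM of at least 5 and at least 50 reads in the higher library. It took 5 at each end between the knockout-labelled libraries and for genes set apart in wild type, and up to 4 members of each list. Predicted-gene names were passed over, a gene the rule selected is not reported here, and a fixed set of receptors, ligands and enzymes was added.

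Both knockout-labelled libraries share 1 wild-type library, which cannot be split. Shared counts were therefore set beside the number from independent lists and beside 100 shuffles of each gene's 3 values among the libraries. Alternatives fixed in advance were a pseudocount of 0.1, no filter, a filter at FPKM 5, median-of-ratios scaling, TPM rescaling, TMM-scaled CPM from edgeR on rounded expected counts, a counting interval on the ratio, and unmatched random lists. Restricting to protein-coding genes, and removing markers of other cell types together with genes at least 10-fold higher in CD44-/-, were added after seeing the data.

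The steps were tested on simulated data with 200 changed genes. Both libraries of each simulated pair were drawn around the wild-type counts, with counting error only. Variation between animals or cultures was left out, so the numbers below do not say how many calls in the real libraries are false. For the library labelled TLR4-/- against wild type (11962 genes), 91 of 100 genes changed 3-fold and 96 of 100 changed 6-fold were called in the right direction, and 33 unchanged genes were called. For CD44-/- against wild type (11970 genes) the numbers were 89, 99 and 33, and between the knockout-labelled libraries (11977 genes) 89, 97 and 32. Of 100 unchanged simulated lists per comparison, 1, 3 and 9 fell outside the limits in that order, where 5 are expected. All simulated pairs came from the same profile, so these numbers do not rank the real comparisons. Lists standing apart in any of them need caution. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16.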

Results

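Gene expression was compared in cultured primary mouse hepatic stellate cells of 3 genotypes, wild type, TLR4-/- and CD44-/-, with 1 library each. TLR4 is the receptor for bacterial lipopolysaccharide, and CD44 is a surface receptor for hyaluronan. The series title frames the question as the effect of lacking either receptor on these cells. Libraries held 24078669, 23659074 and 21460725 expected counts in that order. An FPKM of at least 1 in at least 1 library was reached by 12371 genes, called measured here. No replicates exist in these files, so no difference below has a replicate check, and intervals cover counting error only.

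The targeted genes were examined first. Cd44 (Entrez 12505, chromosome 2, 102811141 to 102901669, GRCm38) stood at 17.2 FPKM in wild type and 2.57 FPKM in the CD44-/- library, a ratio of 0.149 (95% interval 0.130 to 0.170), with 253 reads remaining. Tlr4 (Entrez 21898, chromosome 4, 66827551 to 66846581) stood at 15.8 FPKM in wild type, 16.8 FPKM in CD44-/- and 10.9 FPKM in the library labelled TLR4-/-. The ratio of the last to wild type was 0.693 (0.639 to 0.752), with 1000 reads remaining against 1468. A gene-level value can include reads from outside a deleted part, and the allele is not given in the sources used here. The Tlr4 level therefore does not by itself settle the genotype, and that library is called the library labelled TLR4-/- throughout.

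In the library labelled TLR4-/-, the serine synthesis enzymes Phgdh and Psph and the amino acid transporter Slc7a5 were among the genes furthest above wild type. The endothelial genes Cdh5, Pecam1 and Cldn5, Colec11 and Lcn2 were among those furthest below. Phgdh, which starts that pathway, stood at 128 FPKM against 33.3, 3.84-fold (3.63 to 4.07). Psph, which ends it, was 3.86-fold higher (3.53 to 4.22), and Slc7a5 4.35-fold higher (4.11 to 4.60). Aldh1l2, a mitochondrial folate enzyme, was 5.10-fold higher (4.69 to 5.54). Colec11, a collectin of quiescent stellate cells, stood at 14.1 FPKM against 94.4, 6.72-fold lower (6.09 to 7.43). Lcn2, an acute-phase lipocalin, was 11.04-fold lower (8.71 to 14.2). In all, 126 of 12098 genes were at least 2-fold higher and 326 at least 2-fold lower. With a pseudocount of 0.1 these counts were 214 and 504, and with a filter at FPKM 5 they were 75 and 183.

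Other genes furthest above wild type in that library were Cox6a2, Niban1, Avil, Erdr1 and Cmss1, at 20.8-fold (9.29 to 57.8), 12.4-fold (9.62 to 16.3), 11.6-fold (8.69 to 15.8), 4.42-fold (4.09 to 4.79) and 4.80-fold (3.57 to 6.56). Hmga1, a chromatin protein, was 5.40-fold higher (5.17 to 5.63), but it shares reads with its copy Hmga1b, which was 103-fold lower (74.1 to 144), and both are uncertain. The same holds for Atp6v0c-ps2, a pseudogene that was 386-fold lower (240 to 640). Among endothelial genes, Cdh5, a junctional cadherin, was 13.5-fold lower (10.9 to 17.0), Pecam1 21.9-fold lower (15.1 to 32.9) and Cldn5 18.2-fold lower (10.4 to 34.6). Fcgr2b, Aqp1 and Cadm1 were 32.3-fold (20.03 to 56.0), 17.4-fold (13.5 to 22.7) and 19.3-fold (14.4 to 26.5) lower.

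Stellate cell lists lay below wild type in the library labelled TLR4-/-, as did most lists: of 26 that stood apart, 23 were lower and 3 higher. The activation and contraction list had a median log2 ratio of -0.63 over 18 measured members, below all 10000 random lists, with 6 members at least 2-fold lower and 12 between. Of the 18, 3 lay above 0. Vascular smooth muscle markers, another contractile cell type, had a median of -0.67 over 5 members, 0 of them above 0. Acta2, the smooth muscle actin of activated cells, stood at 81.5 FPKM against 234.7 and Cthrc1 at 0.11 against 2.79. The quiescence list also had a low median, -0.43 over 18 members, with 3 at least 2-fold lower. It included Prelp at 202 FPKM against 849, Bmp10 with a log2 ratio of -1.07 and Steap4 with -0.94. Collagens and matrix had a median of -0.22 over 20 members (percentile 0.54) with none at 2-fold, and Col1a1 stood at 358 FPKM against 588. Endothelial markers had a median of -1.44 over 13 members, with 10 at least 2-fold lower, and macrophage markers -0.51 over 15, with 4 at least 2-fold lower. Cell numbers are not given in the sources used here. A larger share of other cells in the wild-type culture therefore cannot be told apart from lower levels per cell in this library. Endothelial markers were lower in CD44-/- too (-0.95).

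Signalling lists had low or unchanged medians in that library. The inflammatory list had a median of -0.49 over 21 members, below all random lists, with 5 at least 2-fold lower. Among them were Lcn2, Saa3 (7.89-fold lower, 5.15 to 12.6), the monocyte chemokine Ccl2 (2.68-fold lower, 2.37 to 3.05) and Lif (log2 ratio -1.35). Interferon-stimulated genes had a median of -0.24 over 18 members (percentile 0.12), with Ifit3 at 19.2 FPKM against 48.3. TGF-beta pathway genes had a median of -0.42 over 19 members, with 5 at least 2-fold lower. Members of the TLR4 signalling list had a median of 0.00 over 20 members (percentile 26.95) and none passed 2-fold. Its co-receptor Ly96 had a ratio of 1.15 (0.946 to 1.39), the adaptor Myd88 1.04 (0.940 to 1.14) and Cd14 0.662 (0.516 to 0.846). The Notch list had a median of -0.08 over 15 members (percentile 11.51). Within it, Notch3 had a log2 ratio of -1.11, Hes1 a ratio of 0.595 (0.543 to 0.651), Notch1 0.643 (0.616 to 0.672) and the ligand Jag1 1.01 (0.925 to 1.11). Hyaluronan genes had a median of -0.09 over 11 members (percentile 18.275).

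**Figure D1:**
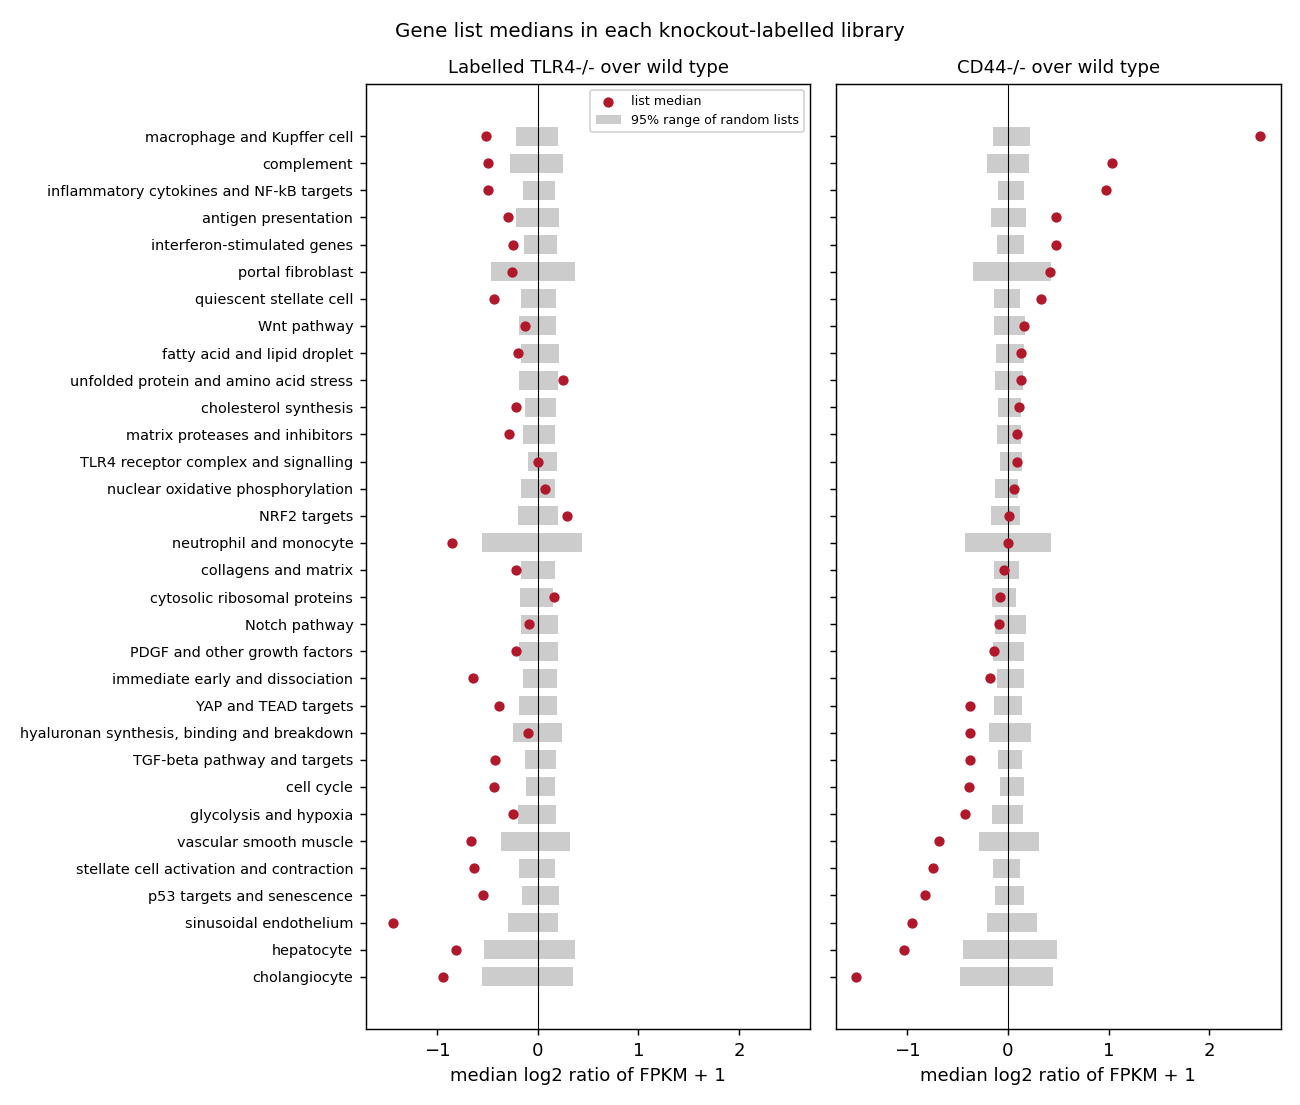
Median log2 ratio of FPKM + 1 for each gene list with at least 3 measured members (points), with the 95% range of 10000 matched random lists (grey bars), for the library labelled TLR4-/- (left) and CD44-/- (right) over wild type. The macrophage list lies at -0.51 on the left and 2.5 on the right, and the stellate activation list at -0.63 and -0.74.

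In the CD44-/- library, macrophage genes were furthest above wild type, and the matrix protease gene Mmp10 was among those furthest below. Lyz2, the macrophage lysozyme, stood at 362 FPKM against 31.4, 11.5-fold (10.7 to 12.4). Mmp12, the macrophage elastase, was 12.6-fold higher (11.9 to 13.3), and the chemokine Ccl6 32.8-fold higher (26.9 to 40.3). Mmp10, a stromelysin, was 9.24-fold lower (8.41 to 10.2). In all, 274 of 12247 genes were at least 2-fold higher and 241 at least 2-fold lower. With a filter at FPKM 5 these counts were 167 and 143, and with a pseudocount of 0.1 they were 391 and 386.

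All 15 measured macrophage markers were at least 2-fold higher in CD44-/-, with a median log2 ratio of 2.5, above all random lists. Further genes at that end were Clec4n (20.2-fold, 16.1 to 25.7), Clec7a (14.4-fold, 12.3 to 17.0), Cd5l (20.5-fold, 15.5 to 27.7), Il1rn (24.8-fold, 18.2 to 34.4) and Wfdc17 (16.0-fold, 11.7 to 22.3). Lilrb4a (18.5-fold, 14.5 to 24.0) and Bcl2a1b (27.7-fold, 15.7 to 54.3) belong to families of similar genes and are uncertain. At the lower end, Alb was 57.1-fold lower (27.5 to 143), Krt18 43.7-fold (18.5 to 136), S100a7a 17.5-fold (8.28 to 44.4), Npw 15.5-fold (6.90 to 43.3) and Pttg1, a mitotic securin, 6.20-fold (4.97 to 7.83). The liver protein gene Mup10 had no read in CD44-/- against 107 in wild type, at least 31.8-fold lower, and belongs to a family of similar genes. Hmga1b and Atp6v0c-ps2 were also lower, 113-fold (79.7 to 167) and 294-fold (192 to 474), with the limit given above. Hepatocyte markers had a median of -1.03 over 4 members (percentile 0.06), and endothelial markers -0.95 over 13, with 6 at least 2-fold lower. Here too, the share of such cells in each culture was not measured.

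Immune lists had higher medians in CD44-/- alongside the macrophage markers. The inflammatory list had a median of 0.98 over 21 members, above all random lists, with 10 at least 2-fold higher and 1 lower. Ptgs2, an inducible cyclooxygenase, was the lower one, at 1.86 FPKM against 7.17, while Il1a, Cxcl1 and Vcam1 had log2 ratios of 1.75, 1.67 and 1.51. Interferon-stimulated genes had a median of 0.47 over 18 members with 1 at 2-fold, Xaf1, at 27.5 FPKM against 5.18. Cd14 had a ratio of 3.58 (3.01 to 4.28), while the TLR4 signalling list had a median of 0.09 over 20 members (percentile 85.72). Ly96 and Myd88 had ratios of 1.09 (0.893 to 1.33) and 1.07 (0.971 to 1.19).

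Stellate cell lists diverged in CD44-/-. Activation and contraction had a median of -0.74 over 18 members, below all random lists, with 6 at least 2-fold lower, among them Cthrc1 at 0.08 FPKM, Postn at 92.5 against 238, S100a6 at 306 against 719 and Actg2 at 1.79 against 5.29. Vascular smooth muscle markers had a median of -0.68 over 5 members, 0 of them above 0. The quiescence list had a median of 0.33 over 18 members, above all random lists, with 1 at 2-fold, Steap4. Of the 18, 17 lay above 0, while Bmp10 went the other way with a log2 ratio of -0.93. Collagens and matrix had a median of -0.04 over 20 members (percentile 31.82), with members on both sides. Col1a1 was 2.87-fold lower (2.83 to 2.92), Eln had a log2 ratio of 1.29 and Col3a1 0.86. TGF-beta genes had a median of -0.37 over 19 members with 4 at least 2-fold lower, including Ltbp1 at -1.60, Inhba at -1.27 and Ccn2 at -1.21. Hyaluronan genes had a median of -0.37 over 11 members (percentile 0.13) with none at 2-fold. The synthases Has1, Has2 and Has3 stayed under 1 FPKM in every library. Notch genes had a median of -0.09 over 15 members (percentile 5.11), with 1 at least 2-fold lower and 5 above 0. Notch4 and Notch3 had log2 ratios of -1.03 and -0.98. Hes1 had a ratio of 0.504 (0.456 to 0.556), Notch1 0.716 (0.685 to 0.748) and Jag1 0.932 (0.846 to 1.03). Acta2 and Timp1 had ratios of 0.631 (0.614 to 0.648) and 0.578 (0.543 to 0.615).

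**Figure D2:**
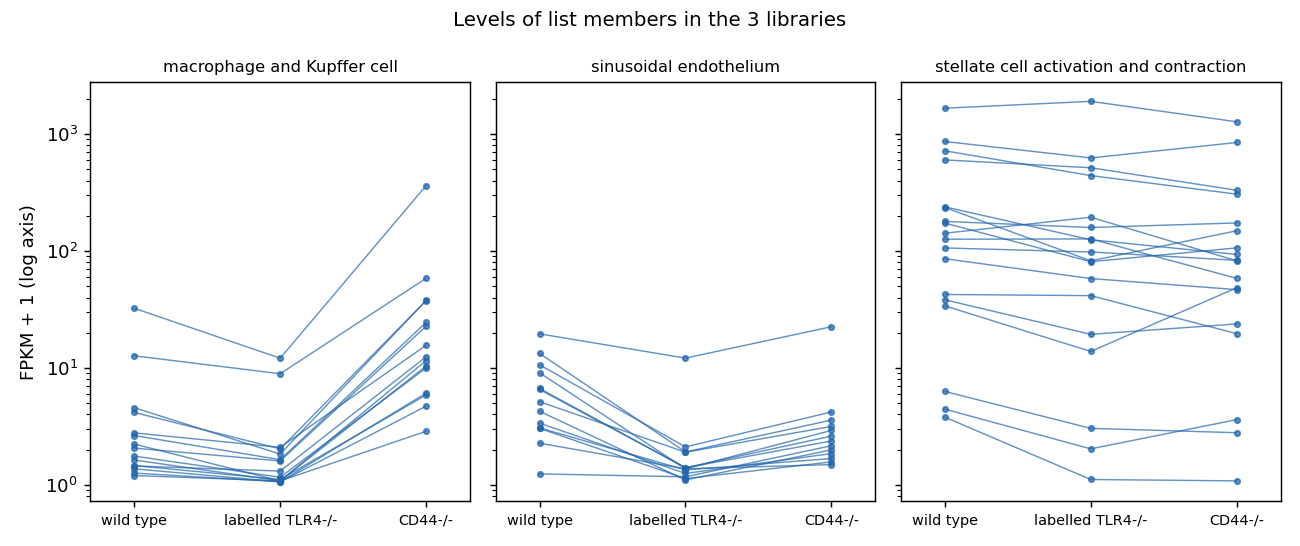
FPKM + 1 (log axis) of each measured member of 3 lists in the 3 libraries, 1 line per gene. The 15 macrophage markers are highest in CD44-/-, where Lyz2 reaches 362 FPKM, and endothelial markers are mostly highest in wild type.

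Compared directly, the knockout-labelled libraries differed most in the macrophage genes, of which 15 of 15 were at least 2-fold lower in the library labelled TLR4-/- (median -3.25). Mmp12, Ccl6, Clec4n, Lyz2 and Wfdc17 were the named genes at that end, with Mmp12 at 4.03 FPKM against 209. At the other end, Klk8 stood at 9.19 FPKM against 0.61, Pttg1 at 29.5 against 5.24, the chromatin protein Hmga2 at 29.6 against 5.89, Slc7a5 at 78.0 against 18.5 and Acsbg1 at 7.61 against 1.14. In all, 161 of 12168 genes were at least 2-fold higher in the library labelled TLR4-/- than in CD44-/-, and 418 lower. With a filter at FPKM 5 these counts were 104 and 265, and with a pseudocount of 0.1 they were 279 and 604. The inflammatory list had a median of -1.19 with 12 of 21 members at least 2-fold lower, interferon-stimulated genes -0.76 with 7 of 18, and quiescence genes -0.55 with 5 of 18. Activation genes had a median of 0.18 (percentile 95.03), TGF-beta genes -0.07 (13.27), collagens -0.02 (21.2), Notch genes -0.02 (36.59), hyaluronan genes -0.01 (43.74) and TLR4 signalling genes -0.01 (32.94). Among activation genes, 3 were at least 2-fold higher in the library labelled TLR4-/- (Timp1, Spp1 and Lox) and 1 at least 2-fold lower (Thbs2).

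Both knockout-labelled libraries were set against the same wild-type library, so their agreement depends on it. Among 11974 genes compared in both, 25 were at least 2-fold higher in both and 129 lower in both. Independent lists would share 1.28 and 6.56. Shuffling each gene's 3 values among the libraries gave means of 63.0 and 135.4, with ranges of 50 to 79 and 115 to 152. The covariance of the log2 ratios was 0.0787, against 0.113 in the shuffles. The observed sharing was therefore not above what 3 equally different libraries give, and part of it may come from the shared control. Another 20 genes were at least 2-fold changed in opposite directions, among them Lyz2, Mmp12, Ccl6, Lcn2 and Ccl2. Their number lay within the shuffled range of 7 to 26 (mean 13.25), but the shuffles counted both senses together. All 20 were lower in the library labelled TLR4-/- and higher in CD44-/-, so the range does not describe this one-sided pattern. The CD44-/- library was set apart from both others by 219 higher and 56 lower genes, wild type by 129 and 25, and the library labelled TLR4-/- by 57 and 108. Across the alternatives these counts ranged from 132 to 287 and 42 to 121 in CD44-/-, 62 to 200 and 15 to 72 in wild type, and 29 to 94 and 87 to 284 in the library labelled TLR4-/-. Genes highest in wild type included Krt18 and Gchfr (9.10 FPKM against 1.19 and 1.16), and wild type was lowest for Cox6a2, Chchd10 (25.9 FPKM against 86.7 and 86.2) and Aldh1l2. The rule also placed Atp6v0c-ps2 and Hmga1b highest and their parents Atp6v0c and Hmga1 lowest in wild type, but these pairs share reads and all 4 are uncertain. Summed, Atp6v0c and its copy had 460 CPM in wild type, 401 in the library labelled TLR4-/- and 466 in CD44-/-, and Hmga1 and its copy 269, 539 and 219, so wild type was neither highest nor lowest for either sum.

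**Figure D3:**
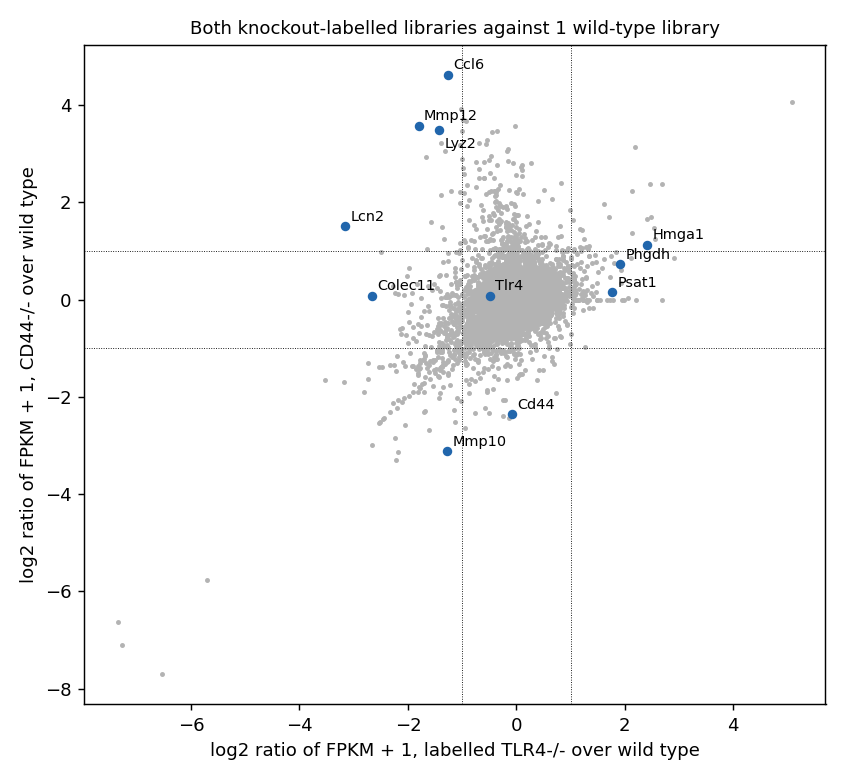
Log2 ratio of FPKM + 1 over wild type in the library labelled TLR4-/- (x axis) and in CD44-/- (y axis), 1 point per measured gene (12371 genes), with 2-fold lines dotted and example genes in blue. Macrophage genes such as Lyz2 lie at the upper left and Mmp10 at the lower left.

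Proliferation and stress lists were also described. The cell cycle list had medians of -0.43 in the library labelled TLR4-/- and -0.39 in CD44-/- over 23 members, with 4 at least 2-fold lower in each. These were the mitotic genes Ccnb2, Cdc20, Ccnb1 and Plk1. The replication helicase gene Mcm2, chosen after its values were seen, stood at 15.3 FPKM in wild type, 30.7 in the library labelled TLR4-/- and 25.3 in CD44-/-. Targets of p53 had medians of -0.54 and -0.82 over 14 members, with Cdkn1a at 303, 185 and 123 FPKM in wild type, the library labelled TLR4-/- and CD44-/-. Immediate early genes had medians of -0.64 and -0.18 over 18 members, with Egr1 at 12.7, 2.41 and 6.39 FPKM. The unfolded protein and amino acid stress list had medians of 0.25 (percentile 99.38) and 0.13 (94.845) over 15 members, with Asns at 30.7, 104.4 and 42.7 FPKM.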

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

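The tests of macrophage RNA and of copies were chosen after the values were seen, and those of the regions around the targeted genes before.

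Lists that stood apart in opposite directions in the knockout-labelled libraries are given here as the median log2 ratio of the library labelled TLR4-/- over CD44-/-. The difference was not tested, since each genotype has 1 library. It was -0.55 for quiescence genes, -1.19 for the inflammatory list, -0.76 for interferon-stimulated genes, -1.63 for complement, -0.92 for antigen presentation and -3.25 for macrophage markers.

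The first pattern is the height of macrophage and immune genes in CD44-/-, with 100% of the 15 measured macrophage markers at least 2-fold higher. A larger share of macrophages cannot be told apart from higher levels per cell, because that count restates the pattern and cell numbers are not given in the sources used here. Per the labels' protocols, liver macrophages had been depleted with beads against CD11b before culture, and differences in that step were not tested. A smaller share stays open for the lower inflammatory list in the library labelled TLR4-/-, where the markers were lower too (-0.51): the loss exceeded the gain in CD44-/- times 0.141, the highest marker ratio, in 15 of 21 members (71.4%), and the median ratio of the 16 with a gain, the first form run, was 0.351, but both assume 1 macrophage profile, and any loss passes the bound in the 5 members without a gain. Whether macrophages bring the complement and antigen presentation gain also stays open without a measured profile: the median gain was 10.9% of that of Lyz2, but B2m gained 280%, H2-D1 197%, H2-K1 130% and Serping1 62.0% of it. The CD44 genotype stays open as an untested biological explanation.

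The second pattern is copies listed high in wild type. Reads moving between parent and copy may account for the height of Atp6v0c-ps2, whose sum with Atp6v0c had a log2 ratio of 0.0856 between wild type and the mean of the knockout-labelled libraries, and of Hmga1b, whose sum with Hmga1 had -0.49. That mean joins unlike libraries: the Hmga1 sum was 269 CPM in wild type, 539 in the library labelled TLR4-/- and 219 in CD44-/-, so shared reads leave a 2.00-fold difference in the library labelled TLR4-/-. They do not account for Gm6644 and its parent Akr1b3, whose sum was 2.40 higher on the log2 scale in wild type. The pairs were first tested as 1 set, which decided nothing, and why reads would be divided otherwise in 1 library was not tested, so a strain variant stays open.

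The third pattern is the surroundings of the targeted genes, where a segment from a donor strain could remain. Within 10 Mb of Tlr4, 4 of 42 genes (9.52%) were at least 2-fold changed, at percentile 97.78 of 11303 windows on other chromosomes, just past the upper limit for standing apart. That result is borderline: 8 draws of 1000 windows with at least 20 genes, the form first run, gave percentiles from 97.18 to 98.40, on both sides of the limit. The windows were placed around measured genes and overlap, so they are not independent. Of the 4 genes, Mup10 and Mup18 are liver protein genes of 1 family that were lower along with hepatocyte markers. Both were also lower in CD44-/- (log2 ratios -2.59 and -2.31), whose targeted gene lies on another chromosome. That leaves Megf9 and Col27a1. Within 10 Mb of Cd44, 3 of 57 genes were changed, at percentile 70.93, so no excess of changed genes was seen there. A segment that changes few genes would not raise this share, so whether one is present stays open.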

How the results depend on the processing

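Restricting to protein-coding genes and removing other-cell-type genes were chosen after seeing the data. The second removed 127 genes: members of the other-cell-type lists and genes at least 10-fold higher in CD44-/- than in both others. Its lower counts of genes higher in CD44-/- follow from this construction. Of 117 recomputed counts, 88 stayed within 1.5 times. Removing the filter changed no count, since the added 1 already keeps genes under 1 FPKM from reaching 2-fold. Fewer genes pass a filter at FPKM 5, and low genes gain from a smaller pseudocount. FPKM sums were 436960 in wild type, 437051 in the library labelled TLR4-/- and 433965 in CD44-/-. TPM rescales each library to the same larger sum, so it is close to a constant multiple of FPKM. The added 1 then weighs less, as with a smaller pseudocount. For other settings the cause was not tested.

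Counts are given as higher and lower, and a count left out stayed within 1.5 times of the main one. With a pseudocount of 0.1 they were 214 and 504 for the library labelled TLR4-/- against wild type. They were 391 and 386 for CD44-/- against wild type, and 279 and 604 between the knockout-labelled libraries. Set apart were 200 and 72 in wild type, 94 and 284 in the library labelled TLR4-/- and 121 lower in CD44-/-, and 257 were changed the same way in both. With a filter at FPKM 5 they were 75 and 183, 167 and 143, and 104 and 265 for those comparisons, with 62 and 15 set apart in wild type, 32 higher in the library labelled TLR4-/-, 135 higher in CD44-/- and 72 changed the same way. TPM gave 47 lower set apart in wild type, 174 lower in the library labelled TLR4-/- and 87 lower in CD44-/-. For genes set apart higher in the library labelled TLR4-/-, TMM gave 35, the counting interval 33 and protein-coding genes 29. Protein-coding genes gave 15 lower in wild type, and removing other-cell-type genes 132 higher in CD44-/-.

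Primary list medians kept their side in 185 of 189 recomputations. Activation genes between the knockout-labelled libraries passed the limit with a pseudocount of 0.1 (0.23), a filter at FPKM 5 (0.28) and unmatched lists (0.18), and Notch genes in the library labelled TLR4-/- without a filter (-0.13). Of 474 for other lists, 447 were the same, 13 passed the limit, 12 no longer did and 2 turned. Both were cholangiocyte medians without a filter, 0.0352 for CD44-/- over wild type and -0.0298 between the knockout-labelled libraries, where unexpressed members enter. All 368 recomputed ratios of named genes kept their direction and side of 2-fold. These genes were picked for the largest or smallest ratios, so this was likely from the outset. It does not cover every ratio of each named gene.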

Other observations

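The serine list and the split of tRNA synthetases were chosen after the data were seen; the test on the synthetases was written before their values were looked at.

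Amino acid synthesis genes formed a group in the library labelled TLR4-/-. Of 11 serine and one-carbon genes, 8 were at least 2-fold higher than in wild type, with a median log2 ratio of 1.23, against 0.14 in CD44-/-. Psat1 stood at 133 FPKM against 38.5. The list includes genes picked from this comparison, so its height is not independent evidence. A response through the transcription factor ATF4 is a candidate explanation, and it predicts higher tRNA synthetases of the kind ATF4 induces. Their median was 0.82 over 12 members, at percentile 100 of the random lists, with 5 at least 2-fold higher. The other synthetases, a comparison set, had a lower median of 0.47 over 8 members but also stood apart (percentile 99.95), so the difference is not specific to the ATF4 set. Among other targets, Asns had a log2 ratio of 1.73 and Trib3 1.31, while Chac1 stood at 5.22 FPKM against 5.28 and Atf4 itself at 129 against 114. A difference in nutrients or culture between single cultures was not tested.

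Further lists are given as medians in the library labelled TLR4-/- and then in CD44-/-, over wild type. Matrix proteases had -0.28 and 0.09, growth factors -0.22 and -0.14, YAP and TEAD targets -0.38 and -0.37, Wnt genes -0.13 and 0.16, complement -0.50 and 1.03 and antigen presentation -0.30 and 0.48. Cholesterol synthesis had -0.22 and 0.11, lipid genes -0.19 and 0.13, glycolysis and hypoxia -0.24 and -0.43, and NRF2 targets 0.29 and 0.01. Ribosomal proteins had 0.16 and -0.07, and nuclear oxidative phosphorylation 0.07 and 0.06. Among other cell types, hepatocyte genes (4 members) had -0.82 and -1.03, cholangiocyte genes (4) -0.94 and -1.50, portal fibroblast genes (5) -0.26 and 0.41, smooth muscle genes (5) -0.67 and -0.68, and neutrophil and monocyte genes (3) -0.85 and 0.00. Without a filter the cholangiocyte medians were -0.0143 and 0.0352, and for the library labelled TLR4-/- the neutrophil and monocyte median was -0.0291 and that of lipid genes -0.0704. The mesothelial list had 2 measured members (-0.44 and -0.56) and the lymphocyte list 1 (0.57 and 0.01). Lists standing apart numbered 26 of 32 for the library labelled TLR4-/- (3 higher, 23 lower) and 18 of 32 for CD44-/- (6 higher, 12 lower), against 1.6 expected for independent genes. Of the 26, the cholangiocyte, neutrophil and lipid lists no longer stood apart without a filter, the neutrophil list also not with TMM (-0.63), and ribosomal proteins not without a filter, with TMM or with unmatched lists (percentiles 97.10, 96.53 and 96.58). Of the 18, the cholangiocyte list no longer did without a filter, while in each library some other lists came to stand apart under an alternative.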
